A study of Mus musculus with 12 samples.

How the data were processed

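The series holds 12 two-colour mouse oligonucleotide arrays of cortical neurospheres in 4 groups of 3: control and prominin cultures at 24 h and at 108 h. Per the labels' protocols, total RNA was extracted with Trizol and cleaned on RNeasy columns. Sample RNA was labelled with Cy5, and a universal reference from whole mouse embryos of gestational day 12 with Cy3, by dendrimer labelling, without a dye swap. Scanner, image software and normalization are not given in the sources used here. Groups came from the sample titles. The labels do not say whether replicates were separate cultures.

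The deposited table holds 21738 probes on 12 arrays, and its values were read as log2 ratios of sample to reference. The labels do not state the direction of the ratio. The deposited values had not been brought to a common scale: array medians of the probes measured on all arrays ran from −2.59 to −0.84. They hold 2 codes. A top code of 16.61 filled 32 to 2540 cells per array, and exact zeros filled 4986 to 8794. Both were set to missing, which left 10404 to 14465 measured probes on the 24 h arrays and 15944 to 16598 on the 108 h arrays. Small whole-number ratios, a mark of dim spots, made up 31.0 to 56.0% of measured values at 24 h and 3.28 to 9.60% at 108 h. The direction of the ratio was checked against gene lists fixed before the data were examined. Neural stem genes lay above the median probe (2.84 after centring), and erythroid genes (−3.27) and genes of the embryo outside the nervous system (−5.05) below it. This is the order that sample over reference would give.

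Before the data were examined, the deposited values were planned to enter the test as they were. The array medians, seen before any test, led to a change: each array was centred on the median of the 4532 probes measured on all 12 arrays. The fit without centring became an alternative, and called 0, 0, 0 and 0 probes in the first 4 comparisons and 7 (2 higher, 5 lower) with time in prominin cultures. The 9155 probes with at least 2 values in every group were tested with limma 3.58.1 in R 4.3.3: 1 mean per group, 5 contrasts (prominin against control at 24 h and 108 h, their difference, and 108 h against 24 h in controls and in prominin cultures), moderated variance, Benjamini-Hochberg adjustment over the probes of a contrast and a threshold of 0.05. The median residual SD was 1.19. Correlations between arrays were 0.604 to 0.783 within groups, 0.568 to 0.781 between prominin and control arrays of the same time, and 0.552 to 0.748 across times.

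Gene names came from a table of the series' probes: 16620 probes had 1 symbol, 113 had several and 5005 had none, 324 of these with an identifier that a RefSeq gene table knows. This annotation can be old. Probes of a gene were averaged, which gave 7796 genes. Before the data were examined 20 gene lists were written from general knowledge: neural stem and radial glia, neurons, astrocytes, oligodendrocyte lineage, cell cycle, interferon and antiviral response, cholesterol synthesis and uptake, hypoxia and glycolysis, endoplasmic reticulum stress, p53 targets, Notch, Wnt and hedgehog targets, membrane protrusions, immediate early genes, microglia and other leukocytes, endothelium and mural cells, fibroblasts and meninges, erythroid cells, embryo outside the nervous system, cytosolic ribosomal proteins, and oxidative phosphorylation. Lists were tested with limma's camera at its preset correlation of 0.01, with fry beside it on the genes measured on all arrays, adjusted over the lists of a contrast. List values under an alternative are medians relative to the median of all genes.

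The text names Prom1 first, then probes with 1 symbol past the threshold whose groups do not overlap. Where fewer passed, it names the next by smallest unadjusted p, up to 5 in each direction, said not to have passed, and up to 4 members of each described list by the same order. Members of further lists were added by that order after the data were seen. Gene models without a name were passed over. Prom1 was also given an exact permutation test.

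Simulated data had 9155 probes and 3 arrays a group, with each probe's moderated spread and its own missing values. Moderation makes the spreads more alike than the measured ones. The noise was drawn independently for each probe. There the prominin comparison at 108 h recovered 1.99, 47.8 and 81.8% of probes changed by 2, 4 and 6 on the log2 scale. The step with time in prominin cultures recovered 2.49, 47.3 and 79.3%. Over 3 simulations there were 29 false calls in the first (beside 4, 96 and 162 recovered) and 14 in the second (beside 5, 95 and 157), so in both their share was above the threshold of 0.05. The ribosomal list shifted by 1 was called in 20 of 20 simulations, and 0 of 400 tests of unshifted lists were called. Since the simulated genes were independent, this does not show how often camera calls lists falsely where genes correlate. On the real arrays, by contrast, other splits into groups did call lists, up to 3 at 24 h and 2 at 108 h. Such splits keep a part of any real difference, so they do not give that rate either.

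Alternatives planned before the data were examined were centring on each array's own median, quantile normalization, probes measured on all arrays, probes with at least 1 value per group, only the groups compared, array weights, robust and no moderation, the replicate number as a term (also within each time), probes averaged to genes, the probe with the highest mean per gene, an estimated correlation between list genes, and each array left out. Those chosen after the data were seen were no centring, centring within 7 classes of probe brightness, codes kept, zeros kept, and the dimmest pair of arrays left out. A probe's brightness class was the number of 24 h arrays, 0 to 6, with a measured value other than a small whole-number ratio. A planned filter on dim signal could not be run, since the table gives no signal. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.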

Results

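RNA was measured in neurospheres, floating clusters of neural stem and progenitor cells, grown from the cerebral cortex of mouse embryos in serum-free medium with basic FGF, EGF and LIF. The 12 arrays fell into 4 groups of 3: control and prominin cultures at 24 h, and the same at 108 h. Prominin cultures had received an adenovirus expressing prominin-1 (CD133), a membrane glycoprotein of cell protrusions that is used as a marker of neural stem cells. The treatment text gives the controls growth medium only, whereas the design text speaks of neurospheres positive for GFP or prominin, so an effect of the virus cannot be separated here from an effect of prominin-1. The treatment text of the 24 h prominin samples also gives 108 h, and the 24 h of their titles was used. Each array compared 1 neurosphere RNA (Cy5) with a shared RNA of whole mouse embryos of gestational day 12 (Cy3), and values are log2 ratios to that reference. Prominin and control stand for cultures so labelled. After centring of the arrays, 0 is the median probe and not the reference, and every change is relative to that probe. The centring took out differences between group means of 0.68 (prominin against control at 24 h), −1.08 (the same at 108 h), 0.69 (108 h against 24 h in controls) and −1.06 (in prominin cultures). The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples.

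Relative to the median probe, genes of neural stem cells and glia had high ratios of neurosphere to whole-embryo RNA. The glial filament gene Gfap averaged 8.56 ± 0.88 (SD, n = 12 arrays), the astrocyte calcium-binding gene S100b 7.54 ± 0.71, the glutamate transporter gene Slc1a3 5.79 ± 0.82 and the glutamine synthetase gene Glul 5.29 ± 1.09. Progenitor transcription factors were also high, with Pax6 at 4.30 ± 1.46 and Sox2 at 3.82 ± 0.63, as were the radial glial genes Fabp7 (3.66 ± 0.49) and Vim (2.76 ± 0.34), whereas Nes, which encodes the filament protein nestin, lay at 0.34 ± 0.85. The oligodendrocyte lineage factors Olig1 (6.06 ± 1.05) and Olig2 (5.05 ± 0.72) were high in the same cultures. Low values were found for the neuronal tubulin gene Tubb3 (−4.16 ± 1.44, n = 11), the proliferation gene Mki67 (−4.05 ± 1.00), the collagen gene Col1a1 (−6.20 ± 1.69) and the transthyretin gene Ttr (−6.61 ± 1.52, n = 10).

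Levels of gene lists fixed before the data were examined are given as the mean over the arrays of each list's median. Neural stem and radial glia genes lay above the median probe at 2.84 ± 0.44 (SD, 12 of 12 arrays above 0; 14 of 19 genes), oligodendrocyte lineage genes at 2.41 ± 1.19 (11 of 12 arrays), astrocyte genes at 2.31 ± 0.85, p53 targets at 1.73 ± 0.40, immediate early genes at 1.06 ± 0.84 and interferon genes at 0.83 ± 0.63. Notch, Wnt and hedgehog targets (0.27), oxidative phosphorylation (0.16), cholesterol genes (0.09), hypoxia and glycolysis (−0.05), microglia (−0.12), membrane protrusions (−0.12), endoplasmic reticulum stress (−0.32) and ribosomal proteins (−0.43 ± 0.79) lay near it. Neuronal genes (−1.92 ± 0.46), cell cycle genes (−2.23 ± 0.62), endothelium (−2.42 ± 0.70), erythroid cells (−3.27 ± 1.77), fibroblasts (−3.98 ± 0.72) and genes of the embryo outside the nervous system (−5.05 ± 1.01) lay below. Leaving out 1 array also removed genes with too few values left, and moved 3 of the 10 levels tried by over 1.5 times. The oligodendrocyte level was 2.23 to 3.99 (highest without prominin 24 h replicate 3, with 4 of 6 genes) and the astrocyte level 2.21 to 3.57 (highest without control 24 h replicate 2, with 8 of 10 genes), so these lists and the neural stem list (2.52 to 3.15) have no fixed order. The erythroid level turned positive without prominin 24 h replicate 3 (0.38, with 3 of 7 genes), and was −0.29 without prominin 24 h replicate 1, −1.10 without prominin 108 h replicate 2, −2.07 without control 24 h replicate 2 and −2.18 without control 108 h replicate 1. The genes named for their level were chosen after the values were seen, and the dyes were not swapped. The median probe itself lay at −1.60 against the reference (mean of 12 arrays), so the levels move with the scaling. Without centring the neural stem list lay at 1.24, oligodendrocyte lineage at 0.81, astrocytes at 0.71 and p53 targets at 0.12 against the reference, whereas immediate early genes (−0.54), interferon genes (−0.77) and the lists after them lay below it.

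**Figure D1:**
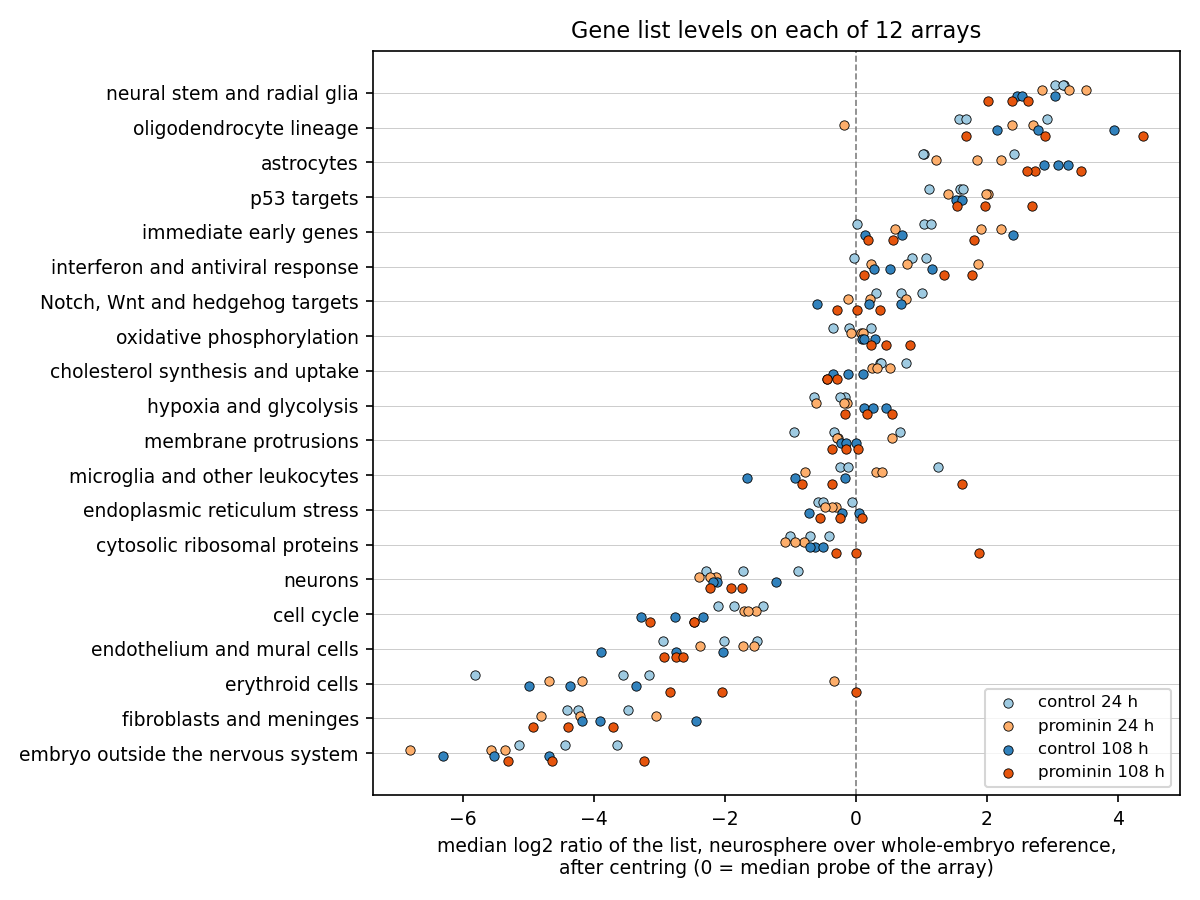
Centred log2 ratio of neurosphere RNA to whole-embryo RNA (0 is the median probe) for each of 20 gene lists; points are the list medians of the 12 arrays, coloured by group. By mean ± SD neural stem genes lay at 2.84 ± 0.44 and genes of the embryo outside the nervous system at −5.05 ± 1.01.

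Prom1, the mouse gene for prominin-1, was measured by 1 dim probe on 9 arrays. At 24 h it lay at 1.19 ± 0.75 (SD, n = 2) in controls and −1.03 ± 0.83 (n = 2) in prominin cultures, a difference of −2.23 (SE 0.95, exact permutation p = 0.333, the smallest that 6 arrangements allow, limma adjusted p = 0.998). At 108 h it lay at −3.06 ± 1.11 (n = 3) in controls and −0.48 ± 0.53 (n = 2) in prominin cultures, a difference of 2.58 (SE 0.87, exact permutation p = 0.1, also the smallest possible, limma adjusted p = 0.717). Without centring the 108 h value of Prom1 was 1.28, and over its 20 alternatives it was 1.28 to 3.33 (limma adjusted p 0.444 to 1.00). The 24 h value was −3.34 to −1.73 over its 20 alternatives (limma adjusted p 0.697 to 1.00), lower in the cultures labelled prominin. Whether the probe detects the transferred sequence, which the labels call R-prominin1, was not tested. Prom1 passed at neither time, so the labels of both 24 h and 108 h remain unchecked.

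**Figure D2:**
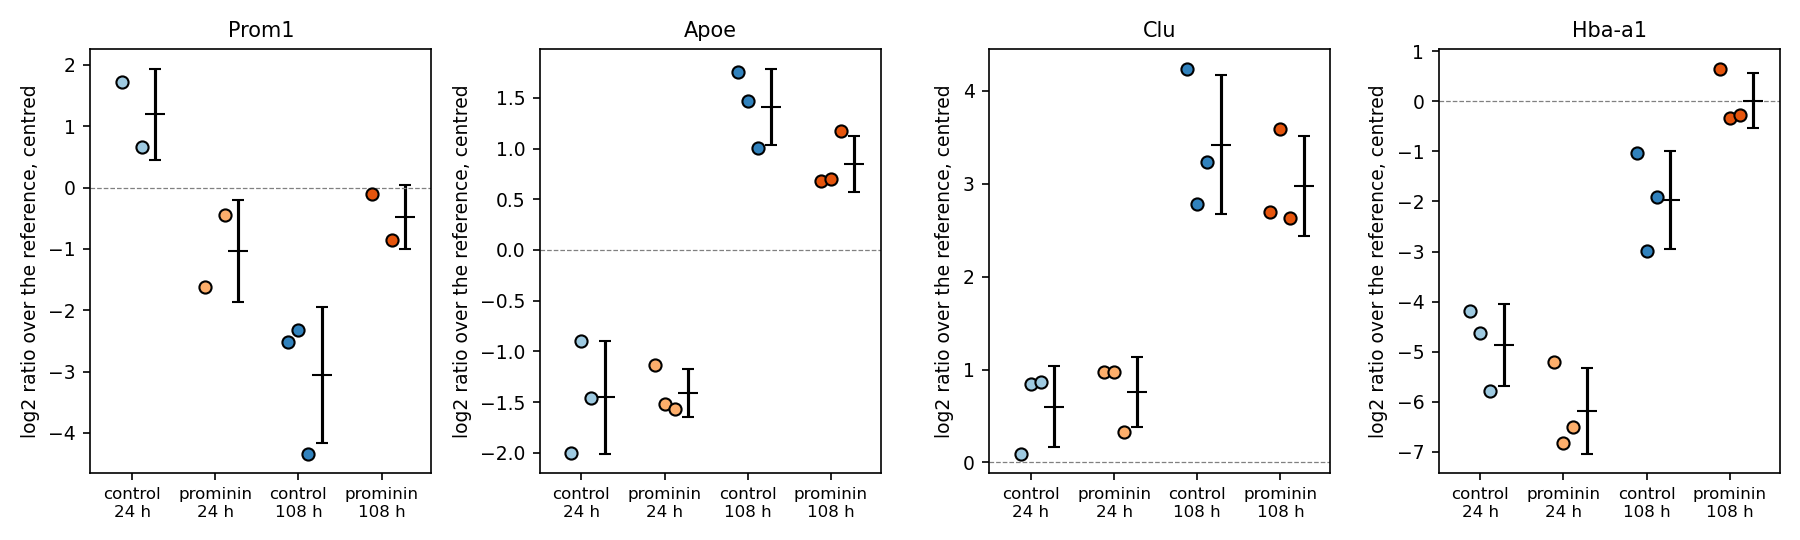
Centred log2 ratio to whole-embryo RNA of Prom1, Apoe, Clu and Hba-a1 in the 4 groups; points are arrays and bars are mean ± SD. Hba-a1 lay at −6.18 ± 0.85 in prominin cultures at 24 h and at 0.01 ± 0.56 at 108 h.

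At 24 h the comparison asked which genes differed between cultures labelled prominin and control, and no gene passed the test. Ndrg1, a gene induced by hypoxia and growth arrest, lay at 2.34 ± 1.01 (SD, n = 2) in controls and −4.90 ± 0.57 (n = 3) in prominin cultures, a difference of −7.25 (SE 0.84, limma adjusted p = 0.0831). Faf2, which encodes a factor of protein degradation at the endoplasmic reticulum, lay 6.28 higher (SE 0.84, limma adjusted p = 0.139; n = 2 and 2). Next by p among genes with higher values were Rbbp5, a histone methyltransferase subunit (3.29, SE 0.70), the Src-family kinase gene Yes1 (3.07, SE 0.77), the carboxylase gene Ggcx (2.56, SE 0.63) and the F-box gene Fbxo22 (2.52, SE 0.63). Among those with lower values were Gnptab, an enzyme of lysosomal targeting (−5.63, SE 1.18), the scaffold gene Grip1 (−5.12, SE 1.00), Vpreb1 (−4.82, SE 0.96) and the deubiquitinase gene Otud4 (−4.30, SE 0.82). All of these had a limma adjusted p of 0.998.

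No list was called at 24 h either. Neural stem genes had a median difference of 0.48 (10 higher, 9 lower, adjusted p = 0.224 by limma's camera), with Notch1 at 2.41 (SE 0.77), Id3 at 2.25 (SE 0.74) and Id1 at 1.47 (SE 0.64). With the exact zeros kept Id3 turned to −0.22. Genes of the embryo outside the nervous system had a median of −0.98 (1 higher, 9 lower, adjusted p = 0.224; Serpina1a −6.28, SE 2.34). Erythroid genes had one of −1.05 (1 higher, 6 lower, adjusted p = 0.224; Hba-x −2.25, SE 0.70). With the zeros kept both medians turned positive (0.005 and 0.29) and Hba-x lay at 3.18. Leaving out 1 array brought lists past the threshold: without control 24 h replicate 3 erythroid (0.0199) and embryonic genes (0.0295), and without prominin 24 h replicate 1 embryonic (0.0235) and neural stem genes (0.0193). Interferon genes, which answer to virus, had a median of 0.08 (10 higher, 5 lower, adjusted p = 0.86); Irf1 lay at 1.53 (SE 1.03), Usp18 at −0.58 (SE 0.50, and 0.10 without centring) and Cxcl10 at −2.46 (SE 1.46; 3.68 with the codes kept). Targets of p53 had a median of 0.43 (8 higher, 4 lower, adjusted p = 0.618), including the apoptosis gene Bbc3 (2.19, SE 0.91) and the p53 ligase gene Mdm2 (2.04, SE 1.16). Immediate early genes had a median of 0.20 (adjusted p = 0.86), with Fos at −2.09 (SE 0.75). The adjusted p of the other 14 lists was 0.485 to 0.946, among them membrane protrusions, where prominin-1 sits (median 0.08, 9 higher, 7 lower; 0.885).

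At 24 h limma called 0 of 9155 probes, with and without moderation of the variance. There were 419 probes at an unadjusted p under 0.05 (176 higher, 243 lower), where chance gives 458. Of the list members only Ndrg1 passed when adjusted over the list alone (9.6e-05). The median SE of a probe was near 1 on the log2 scale, and with 3 arrays a group the smallest exact p is 0.1.

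At 108 h the same comparison asked what differed after longer culture, and genes for cytosolic ribosomal proteins were higher as a group in prominin cultures, relative to the median probe. Of 21 such genes 20 were higher and 1 lower, with a median difference of 1.20 (adjusted p = 2.18e-08 by limma's camera). The call did not hold with an estimated correlation between genes (adjusted p = 0.98, the top of a range from 4.0e-13 over 27 alternatives), nor by limma's rotation test fry (adjusted p = 0.131). Of the 10 splits of the 6 arrays into groups of 3, 6 called at least 1 list by camera, the real one included. Rpl6 lay 1.44 higher (SE 0.56), Rpl35 1.40 (SE 0.55), Rpl19 1.38 (SE 0.57) and Rps14 1.37 (SE 0.53). No member passed when adjusted over the list alone. The list median per array was 0.00, −0.31 and 1.88 in prominin cultures and −0.63, −0.70 and −0.51 in controls. Without prominin 108 h replicate 3 the difference was 0.63 (adjusted p = 0.00771). These values are centred, and the centring took out a difference of −1.08 between the 108 h groups. That is near the ribosomal difference in size and opposite in sign, so the list was not shown to be higher against the reference itself. The fit without centring cannot show this, since its list values are relative to the median of all genes. Erythroid and embryonic genes also had higher values (medians 1.42 and 0.85, adjusted p = 0.2 each), among them the globin genes Hba-a1 (1.99, SE 0.72), Hba-x (1.99, SE 0.77) and Hbb-y (1.42, SE 0.91), the anion exchanger gene Slc4a1 (3.76, SE 1.96) and the albumin gene Alb (2.04, SE 0.91). The erythroid value was −0.32 without prominin 108 h replicate 1, and the embryonic list was past the threshold without prominin 108 h replicate 2 (0.0498).

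**Figure D3:**
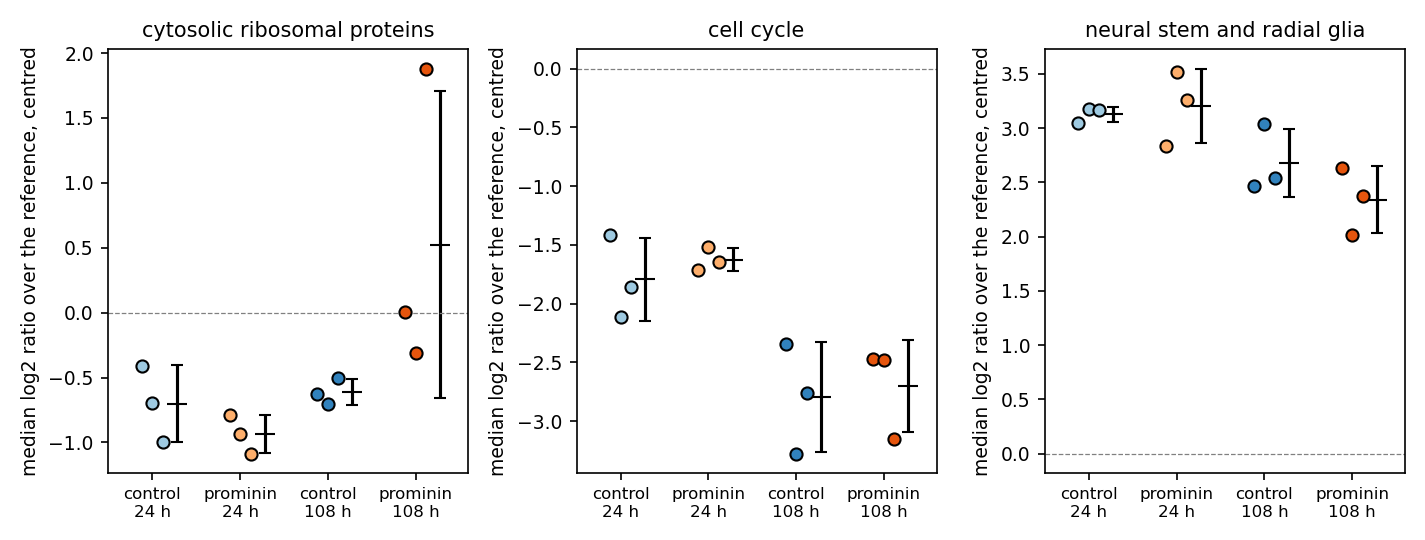
Centred median log2 ratio to whole-embryo RNA of the ribosomal protein, cell cycle and neural stem lists in the 4 groups; points are arrays and bars are mean ± SD. The ribosomal list lay at −0.61 ± 0.10 in controls and 0.52 ± 1.18 in prominin cultures at 108 h.

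No single gene passed at 108 h. Crkl, which encodes an adaptor of growth factor signalling, lay at 7.0 ± 0.24 (SD, n = 2) in controls and 0.68 ± 0.59 (n = 3) in prominin cultures, a difference of −6.32 (SE 0.90, limma adjusted p = 0.276). The phosphatase subunit gene Ppp2r3c lay at −6.28 (SE 0.88, limma adjusted p = 0.347), but at 0.15 with probes averaged to genes. The ligand gene Wnt7a lay at 5.38 ± 0.63 in controls and 2.15 ± 0.57 in prominin cultures (−3.23, SE 0.64, n = 3 each), followed by the kinase gene Camk2g (−4.51, SE 0.96) and the centrosomal gene Cep89 (−3.87, SE 0.81). Higher values were seen for the hair keratin gene Krt33a (6.18, SE 1.27), Sh3bgr (6.17, SE 1.35), the sodium/calcium exchanger gene Slc8a1 (3.41, SE 0.79), the arginine methyltransferase gene Prmt3 (3.04, SE 0.73) and the cap-binding translation factor gene Eif4e (2.89, SE 0.66). For Wnt7a and the genes after it the limma adjusted p was 0.655.

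Stem cell and lineage lists gave no call at 108 h. Neural stem genes had a median of −0.04 (8 higher, 11 lower; Msi1 −5.77, SE 1.99; Sox1 1.94, SE 1.16), neuronal genes 0.05 (9 and 9; Syt1 −3.68, SE 1.42; Nefm −2.38, SE 1.24), astrocyte genes −0.45 (2 and 8) and oligodendrocyte lineage genes 0.44 (4 and 2), with camera adjusted p of 0.982, 0.982, 0.875 and 0.982. Cldn11, the claudin gene of myelin, lay at −2.78 (SE 0.79) and passed when adjusted over the list alone (0.028). Cholesterol genes went both ways (5 higher, 10 lower; median −0.32), with Lss at 2.32 (SE 0.73), Sc5d at −1.91 (SE 0.76), Srebf2 at −1.60 (SE 0.65) and Cyp51 at −2.61 (SE 1.26). So did membrane protrusions (7 and 9; median −0.20), with Slc9a3r2 at 5.54 (SE 1.57), Pls3 at 1.55 (SE 0.68) and Ezr at −2.13 (SE 1.04). Interferon genes had a median of 0.24 (Irf1 1.99, SE 0.92; Stat2 −1.42, SE 0.76) and p53 targets one of 0.03 (Phlda3 1.44, SE 0.54). Cell cycle (0.43, 15 and 10, adjusted p = 0.58), oxidative phosphorylation (0.28, 18 and 6; 0.58), immediate early genes (0.31), microglia (0.26), endothelium (0.21), fibroblasts (−0.01), endoplasmic reticulum stress (−0.14), hypoxia (−0.19) and Notch, Wnt and hedgehog targets (−0.08) were not called. Of the probes limma called 0 of 9155, also without moderation, with 624 at an unadjusted p under 0.05 (301 higher, 323 lower).

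The interaction asked whether the difference between prominin and control cultures changed from 24 h to 108 h. Ribosomal protein genes differed most by p, with a median interaction of 1.62 (20 higher, 1 lower, adjusted p = 7.1e-06 by limma's camera), including Rps14 (1.92, SE 0.76) and Rpl35 (1.88, SE 0.77). Erythroid genes had a median of 2.67 (5 higher, 2 lower, adjusted p = 0.0351) and genes of the embryo outside the nervous system 1.43 (8 higher, 2 lower, adjusted p = 0.0246). With an estimated correlation none of these 3 lists was called (adjusted p = 0.634 each), nor by fry (0.159 for ribosomal proteins, 0.528 for the others). Members were Hba-x (4.23, SE 1.04), Hba-a1 (3.30, SE 1.01), Hbb-y (2.67, SE 1.45), Serpina1a (7.48, SE 3.14), Ttr (3.44, SE 1.51), Alb (3.26, SE 1.28) and the fibrinogen gene Fgb (2.64, SE 1.41). Adjusted over the list alone, Hba-x (0.0227), Hba-a1 (0.0252) and Ndrg1 passed.

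Across 27 alternatives the ribosomal interaction was past the threshold in 26 (adjusted p 1.3e-09 to 0.634), the erythroid interaction in 9 (0.00933 to 0.835) and the embryonic interaction in 13 (0.00376 to 0.846). With the codes kept the embryonic median turned to −0.31, and Hba-x turned to −1.63. Leaving out 1 array ended the erythroid call in 10 of 12 cases (adjusted p 0.0583 to 0.652), all but control 24 h replicate 3 and prominin 108 h replicate 3, and without prominin 108 h replicate 1 the value was 0.68. The embryonic call was lost without control 24 h replicate 1 (0.846) or 2 (0.476), prominin 24 h replicate 2 (0.242) or 3 (0.166), control 108 h replicate 2 (0.114) and prominin 108 h replicate 1 (0.136). Without prominin 108 h replicate 3 the ribosomal interaction was 0.86 (adjusted p = 0.00955). Neural stem genes (median −0.46, 6 higher, 13 lower) and cholesterol genes (−1.10, 4 and 11) had an adjusted p of 0.386, and the other 15 lists 0.952 to 0.996.

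No single gene passed the interaction test. Ndrg1 (8.23, SE 1.19, limma adjusted p = 0.252) and Crkl (−8.13, SE 1.21, adjusted p 0.252) came first. They were followed by Ppp2r3c (−8.02, SE 1.19, adjusted p 0.352) and Wnt7a (−5.98, SE 1.01, adjusted p 0.427). After these came the galectin gene Lgals12 (7.41, SE 1.42), the calcium channel gene Cacna1a (6.42, SE 1.32), Vpreb1 (6.21, SE 1.30), the dehydrogenase gene Hsd17b14 (−5.48, SE 1.03), the fatty acid desaturase gene Fads2 (−5.41, SE 1.10) and Uimc1 (4.95, SE 1.20). Prom1 had a value of 4.80 (SE 1.27; adjusted over the list alone 0.066). In all limma called 0 of 9155 probes, also without moderation, with 545 at an unadjusted p under 0.05 (311 higher, 234 lower).

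The comparison of 108 h with 24 h in controls asked what went with culture time, and cell cycle genes fell as a group relative to the median probe. Of 25 such genes 20 were lower and 5 higher at 108 h, with a median difference of −1.15 (adjusted p = 0.00671 by limma's camera; 0.0797 with an estimated correlation; 6.63e-04 to 0.336 over 27 alternatives, 22 of them past the threshold). The list lay at −1.79 ± 0.35 at 24 h and −2.79 ± 0.47 at 108 h (SD, n = 3 arrays each). The mitotic kinase genes Cdk1 (−3.71, SE 1.02) and Aurka (−2.03, SE 0.85) and the replication genes Mcm3 (−3.02, SE 1.23) and Gins2 (−2.47, SE 1.06) were among the members. The call was also lost with the codes kept (−0.56, adjusted p = 0.336), with quantile normalization (−0.70; 0.204), with the zeros kept (−0.79; 0.178) and without control 24 h replicate 1 (−0.92; 0.0559).

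Apoe and Clu had higher values at 108 h in controls, but did not pass over all probes. The lipoprotein gene Apoe went from −1.46 ± 0.55 to 1.41 ± 0.38 (2.87, SE 0.53, n = 3 each, limma adjusted p = 0.252) and the secreted chaperone gene Clu from 0.60 ± 0.44 to 3.42 ± 0.75 (2.82, SE 0.59, adjusted p 0.397). Adjusted over the list alone Apoe (0.00155), Clu (0.00231), Id3 (3.61, SE 0.74, adjusted p 0.009) and Hba-a1 (2.89, SE 0.72, adjusted p 0.0127) were past the threshold with higher values. With lower values were Prom1 (−4.25, SE 0.86, adjusted p 0.009), Ndrg1 (−6.94, SE 0.92, adjusted p 2.97e-04) and the stress gene Gadd45a (−2.09, SE 0.54, adjusted p 0.028). The Prom1 value rests on 1 dim probe, measured on 2 control arrays at 24 h and 3 at 108 h. All its measured 24 h values were small whole-number ratios, so a fall of Prom1 with time is weakly founded. Astrocyte genes as a list had a median of 0.26 (6 higher, 4 lower; camera adjusted p = 0.35), with Gfap at −1.04 (SE 0.74, and 0.06 with the replicate number within each time as a term) and S100b at −0.69 (SE 0.64). Oxidative phosphorylation had a median of 0.25 (16 higher, 8 lower, adjusted p = 0.0518), with Cycs at 2.54 (SE 1.01) and Sdhc at 1.21 (SE 0.61). It was past the threshold in 6 of 27 alternatives (adjusted p 2.30e-04 to 0.814). These were codes kept (2.30e-04), no centring (0.00204), zeros kept (0.0036), at least 1 value per group (0.0441), and without control 24 h replicate 2 (0.00685) or prominin 24 h replicate 1 (0.0474). The other 17 lists, neural stem (0.10) and ribosomal proteins (−0.04) included, had an adjusted p of 0.545 to 0.958. By limma's rotation test fry, on the members measured on all arrays, 3 lists were called here. These were cell cycle (12 genes, adjusted p = 0.0019), hypoxia and glycolysis (8 genes, 0.00576) and astrocytes (8 genes, 0.0126). By camera hypoxia and glycolysis had a median of 0.58 (9 higher, 3 lower, adjusted p = 0.577).

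No single gene passed between the times in controls. By p the first were Ndrg1 (limma adjusted p = 0.151) and the proliferation gene Pimreg (−3.41, SE 0.54, adjusted p 0.151). Then came Zfp455 (5.09, SE 0.70, adjusted p 0.158), Crkl (5.37, SE 0.90, adjusted p 0.221), Ppp2r3c (4.94, SE 0.80, adjusted p 0.252), the tumour suppressor gene Rassf1 (−4.04, SE 0.69, adjusted p 0.252), the mitotic gene Cdca3 (−4.53, SE 0.89, adjusted p 0.328) and the Hippo kinase gene Lats2 (−4.60, SE 0.86, adjusted p 0.341). Crkl, Ppp2r3c and Ndrg1 recur because the comparisons share arrays. Of the 9155 probes limma called 0, also without moderation, with 635 at an unadjusted p under 0.05 (255 higher, 380 lower).

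In prominin cultures the same step from 24 h to 108 h gave 2 probes past the threshold, both higher at 108 h. The alpha-globin gene Hba-a1 rose by 6.19 (SE 0.72, limma adjusted p = 0.0122; 0.00236 to 0.625 over 28 alternatives), from −6.18 ± 0.85 to 0.01 ± 0.56 (SD, n = 3 each). A probe with no gene name, AF071431, rose by 5.97 (SE 0.61, limma adjusted p = 0.0066; 8.24e-04 to 0.625 over 27 alternatives), from −7.20 ± 0.54 to −1.23 ± 0.16. Its call was lost in 2 of these, with only the groups compared (0.168) and with the replicate number within each time as a term (0.625). In controls the values at 108 h were also above those at 24 h, from −4.86 ± 0.83 to −1.98 ± 0.98 for Hba-a1 and from −5.94 ± 1.01 to −1.95 ± 0.27 for AF071431. The call of Hba-a1 was lost in 7 of the 28 alternatives: with only the groups compared (0.184), with the replicate number within each time as a term (0.625), and without prominin 24 h replicate 2 (0.0722) or 3 (0.0721) or prominin 108 h replicate 1 (0.0821), 2 (0.0503) or 3 (0.0509).

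Of the lists, 6 were called with time in prominin cultures by limma's camera. Ribosomal proteins were higher (median 1.49, 19 higher, 2 lower, adjusted p = 8.44e-10, 0.341 with an estimated correlation), with Rps14 at 2.63 (SE 0.53), Rps16 at 2.32 (SE 0.56), Rps23 at 2.12 (SE 0.64) and Rpl35 at 2.03 (SE 0.55). Adjusted over the list alone, 8 members passed. Genes of the embryo (1.11, 8 and 2), erythroid genes (0.98, 5 and 2) and oxidative phosphorylation (0.48, 22 and 2) followed at an adjusted p of 0.0178 each (0.409 each with an estimated correlation). Their members included Alb at 3.92 (SE 0.91), Ttr at 3.04 (SE 1.06), Afp at 2.03 (SE 0.88), Hba-x at 4.56 (SE 0.77), Hbb-y at 3.22 (SE 1.02), Cox7a2 at 2.5 (SE 0.91) and Cox6c at 1.52 (SE 0.57). Cell cycle genes were lower (−0.65, 8 higher, 17 lower, adjusted p = 0.0449), with Aurka at −2.61 (SE 0.95), Cdk1 at −2.61 (SE 1.02) and Rrm2 at −1.65 (SE 0.67). So were cholesterol genes (−0.80, 4 and 11; 0.0459), with Srebf2 at −2.27 (SE 0.65) and Fdft1 at −1.66 (SE 0.54). Both had an adjusted p of 0.302 with an estimated correlation. No list was called by fry (smallest adjusted p 0.0649).

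With the zeros kept, the erythroid and embryonic medians in prominin cultures turned to −0.27 and −0.44 and Hba-x, Ttr and Afp to −0.34, −0.13 and −0.66. Without prominin 108 h replicate 1 the erythroid value was −0.45. The ribosomal call with time held in 25 of 27 alternatives (adjusted p 6.9e-14 to 0.341), and that of the embryonic list in 17 (7.49e-04 to 0.957). It held for oxidative phosphorylation in 17 (0.00783 to 0.567), for erythroid genes in 13 (4.43e-04 to 0.995), for cholesterol genes in 8 (0.00997 to 0.302) and for cell cycle genes in 5 (0.0134 to 0.508). The ribosomal value was 0.89 without prominin 108 h replicate 3, and oxidative phosphorylation lost its call without that array (0.241) or prominin 24 h replicate 3 (0.0588). The embryonic call was lost without prominin 24 h replicate 1 (0.0535), 2 (0.0659) or 3 (0.0588), or prominin 108 h replicate 1 (0.155). The erythroid call was lost with 1 array left out in 8 of 12 cases (0.0738 to 0.222). The exceptions were control replicate 3 of either time, prominin 24 h replicate 2 and prominin 108 h replicate 3. Cell cycle genes kept theirs only without control 24 h replicate 2 or 3, and cholesterol genes only without these or prominin 108 h replicate 2.

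Single genes just outside the threshold with time in prominin cultures were the ribosomal stalk gene Rplp1 (3.77, SE 0.59), Zfp455 (5.70, SE 0.77), the milk protein gene Lalba (5.59, SE 0.82), the recombination gene Rad52 (3.15, SE 0.54), the collagen gene Col5a3 (−5.53, SE 0.91), the syntaxin-binding gene Stxbp3 (−4.18, SE 0.67) and the glycosyltransferase gene B3galnt1 (−4.87, SE 0.83), each with a limma adjusted p of 0.0888. The EGF receptor inhibitor gene Errfi1 (−4.91, SE 0.93) and Smoc1 (−3.43, SE 0.67) followed at 0.166. Adjusted over the list alone, Apoe (2.26, SE 0.52, adjusted p 0.0104) and Clu (2.21, SE 0.58, adjusted p 0.0137) had higher values here too, though Clu turned to −4.52 with the codes kept. So had the stress gene Ddit3 (3.69, SE 0.85, adjusted p 0.0195), and the membrane linker gene Msn was lower (−3.69, SE 0.70, adjusted p 0.00694). Of 9155 probes 807 were at an unadjusted p under 0.05 (395 higher, 412 lower). The 24 h and 108 h arrays also differed in scanner output, so culture time may coincide with an array batch.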

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

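Of the tests here, the use of 1 left-out array (a setting planned before the data were examined) as a test of the ribosomal pattern, the one of embryo RNA or other embryonic cells, the comparison of array batches, the abundant genes per array and the splits that kept the 108 h groups were chosen only after the results were seen.

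Relative to the median probe, ribosomal protein genes were higher in prominin cultures at 108 h by a median of 1.20. They differed between the times by 1.62 in the interaction test. An estimated correlation ends both camera calls (adjusted p = 0.98 and 0.634). The centring had taken out a difference of −1.08 between the 108 h groups. For a trend with spot brightness, abundant genes outside the translation machinery had a median of 0.0938 (37 of 50 measured, bootstrap −0.01 to 0.38). This lay below 0.60, a cut-off chosen in advance, so a smaller trend behind a part of the change is not excluded. Of random lists matched on brightness class and mean ratio, 95% lay between −0.43 and 0.37. The brightest class held 2565 of the 9155 tested probes, so brightness within it was not matched. The bootstrap and the random lists drew genes independently, so their ranges leave out correlation between genes and do not settle this. On prominin 108 h replicate 3 the abundant genes also stood highest (0.70, against −0.23 to 0.36 on the other 11 arrays) beside a ribosomal median of 1.88, so a part of the change on that array stays open. Without that array the adjusted p was 0.007714, so 1 array is not the whole of it by the preset correlation, but the size dropped to 0.63 (range of adjusted p over alternatives 4.0e-13 to 0.98). The list statistic at 108 h was 6.103 (highest other 5.516, 1 of 10 splits as large, too few for a share under 0.05), and that of the interaction, 5.096, was reached in 2 of 100 splits (highest other 5.32), but the 12 splits that kept the 108 h groups gave 4.26 to 5.32 and the others up to 4.90, so this share is no separate evidence from the 108 h comparison.

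Erythroid genes and genes of the embryo outside the nervous system had higher values in prominin cultures at 108 h relative to 24 h, with median interactions of 2.67 and 1.43, calls that an estimated correlation ends (adjusted p = 0.634 each) and that held in 9 and 13 of 27 alternatives. A candidate explanation is the compression of ratios of genes far below the reference: the upper end of the middle 95% of matched random lists was 1.625, just above the 1.60 of both lists together. For RNA of whole embryos or of other embryonic cells, fibroblast and endothelial genes gave a median of 0.37 (21 genes, bootstrap −0.21 to 1.41). This range spans 0.80, the cut-off chosen for this test, so this explanation cannot be told apart. No sort or gate named in the labels would remove such cells. Hba-a1, measured on 12 arrays, had an interaction of 3.30 and Hba-x, measured on 9, one of 4.23, and the table gives no signal by which to rank their abundance.

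Cell cycle genes were lower at 108 h than at 24 h in controls, by a median of −1.15. An estimated correlation ends the camera call (adjusted p = 0.0797), whereas fry called the list on its members measured on all arrays. For compressed ratios on the dim 24 h arrays, the median of −1.15 lay below the lower end of the middle 95% of matched random lists (−0.83). These lists leave out correlation between genes. Small whole-number ratios were at least 31.04% on every 24 h array and at most 9.60% on every 108 h array, so array batch and culture time cannot be told apart. The list statistic was 3.588 and the highest of the other splits 2.278 (1 of 10 splits as large, too few for a share under 0.05).

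Counts of called probes in other splits of the arrays were as follows. At 24 h all 10 splits gave as many as the real 0 (highest other 0; 419 probes at an unadjusted limma p under 0.05), at 108 h all 10 as many as 0 (highest other 0; 624), and in controls with time all 10 as many as 0 (highest other 0; 635). In prominin cultures with time 1 of 10 splits gave as many as the real 2 (highest other 1). In these 4 comparisons 10 splits are too few for a share under 0.05. For the interaction all 100 splits gave as many as the real 0 (highest other 0; 545). Where the real count is 0 every split gives as many, so these counts say nothing about chance. Lists called by camera in the real split and at most in another were 0 and 3 at 24 h, 1 and 2 at 108 h (6 of 10 splits called as many), 3 and 3 in the interaction (2 of 100), 1 and 1 with time in controls (2 of 10) and 6 and 1 in prominin cultures (1 of 10). Camera with its preset correlation therefore called lists in splits other than the real one, and a list call at 24 h or 108 h is weak evidence by itself. Every other split keeps most arrays of a real group together, and so a part of any real difference. The splits thus do not measure how often camera calls lists falsely.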

How the results depend on the processing

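No centring, centring within brightness classes, codes kept, zeros kept and the dimmest pair left out were alternatives chosen after the data were seen; the others were planned. Of 4149 alternative values of 163 tested gene and list results, 4122 kept their direction and 27 were reversed. Of those that kept it, 123 lost the threshold and 28 came past it. Many of these genes were named for a small p in these same data, so a kept direction is little evidence. Of the levels of 10 lists run under alternatives, that of erythroid cells was reversed; without centring, levels of 5 of the other 10 lists turned negative (immediate early −0.54, interferon −0.77, Notch, Wnt and hedgehog targets −1.33, oxidative phosphorylation −1.44, cholesterol −1.51). List values here are relative to the median of all genes. Where not said otherwise, the cause was not tested.

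With codes kept, limma called 25 probes at 24 h (14 higher, 11 lower) and 17 in the interaction (10 and 7). It called 11 with time in controls (0 and 11) and 16 with time in prominin cultures (2 and 14). A kept top code lies above every measured value by construction, whereas a kept zero lies within the measured range. Keeping the codes called 2 lists with time in prominin cultures and 1 in the interaction. It turned Id3 (−0.22), Cxcl10 (3.68) and Hba-x (3.18) at 24 h, and Hba-x in the interaction (−1.63). With time in prominin cultures it turned Hba-x (−0.34), Ttr (−0.13), Afp (−0.66) and Clu (−4.52). For Clu this came from further probes that entered the gene average, since the probe tested in the main fit held no code. The erythroid and embryonic lists turned at 24 h (0.25 and 0.0277), and the embryonic list in the interaction (−0.31) and with time in prominin cultures (−0.57). Cell cycle genes in controls lay at −0.56 (adjusted p = 0.336). With zeros kept, 1 probe was called at 24 h and 1 at 108 h, and 3 lists with time in prominin cultures. Id3 (−0.22), Hba-x (3.18, −1.63 and −0.34), Ttr (−0.13), Afp (−0.66), the 24 h erythroid and embryonic lists (0.29 and 0.005) and the same lists with time in prominin cultures (−0.27 and −0.44) turned. Cell cycle genes lay at −0.79 (adjusted p = 0.178).

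Without centring, 7 probes were called with time in prominin cultures (2 higher, 5 lower), 0 in the other 4 comparisons (659, 1722, 1918 and 924 at an unadjusted limma p under 0.05) and 2 lists in controls with time; Usp18 at 24 h turned to 0.10. Quantile normalization called 0 lists in controls with time (cell cycle −0.70, adjusted p = 0.204), 3 in prominin cultures with time and 1 in the interaction. Centring on the array's own median called 3 lists in prominin cultures. Only probes measured on all arrays gave 2 probes in controls with time (1 and 1), 21 in prominin cultures (15 higher, 6 lower), and 2, 3 and 1 lists in controls, prominin cultures and the interaction; a smaller number of tests is part of this by construction. Probes with at least 1 value per group gave 2, 2 and 1 lists. Without moderation 7 probes were called with time in prominin cultures (6 higher, 1 lower), with only the groups compared 0, with probes averaged to genes 1 (and Ppp2r3c at 108 h at 0.15). Array weights called 1 list in the interaction. Without the dimmest pair 3 lists were called in prominin cultures with time and 1 in the interaction. Fewer genes then had enough values. The level of the oligodendrocyte lineage was 5.05 (3 of 6 genes), that of erythroid cells −0.47 (4 of 7) and that of the embryo outside the nervous system −3.59 (4 of 10).

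An estimated correlation called 0 lists at 108 h (ribosomal proteins 1.20, adjusted p = 0.98), 0 in the interaction, 0 in controls with time (cell cycle −1.09, adjusted p = 0.0797) and 0 in prominin cultures. The ranges over alternatives were 4.0e-13 to 0.98 for ribosomal proteins at 108 h and 6.63e-04 to 0.336 for cell cycle genes in controls. The replicate number within each time called 0 probes and 0 lists with time in prominin cultures, and Gfap in controls turned to 0.0562. The replicate number as a term called 0, 0, 0, 0 and 2 probes and 0, 1, 3, 1 and 5 lists, with Prom1 at −3.20 and 3.04. The labels link replicates across groups by a number only. In deviations from the group means, over 4532 probes, same-numbered arrays of a time correlated at 0.02 to 0.12 (median 0.07, 2 of 6 pairs over 0.1). Differently numbered arrays of a time correlated at −0.12 to 0.05 (median −0.03, 12 pairs). Among arrays of other groups at either time, 9 of the 12 arrays correlated best with their own number. A weak pairing by number, which the main fit left out, therefore stays possible.

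Leaving out each array gave 0 to 1 called probes at 24 h (1 without control 24 h replicate 2) and 1 to 3 with time in prominin cultures. Lists called were 0 to 2 at 24 h, 1 to 2 at 108 h, 1 to 4 in the interaction, 0 to 3 in controls with time and 1 to 6 in prominin cultures. Ribosomal proteins at 108 h were 0.63 to 1.62 and cell cycle genes in controls −1.30 to −0.83 (without control 24 h replicate 1 −0.92, adjusted p = 0.0559). The level of the erythroid list was −3.34 to 0.38 (highest without prominin 24 h replicate 3, where 3 of its 7 genes still had enough values), its 108 h difference −0.32 to 1.99 and its difference with time in prominin cultures −0.45 to 2.12 (both lowest without prominin 108 h replicate 1).

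These results are limited by 3 arrays a group, a median SE near 1 on the log2 scale, and a ribosomal call that the estimated correlation ends.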

Other observations

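Genes of signalling and stress had single large differences at 108 h that were not described above, and the choice to look at them was made after the results were seen. In prominin cultures the unfolded protein response factors Atf4 (1.48, SE 0.48) and Ddit3 (2.12, SE 0.85) lay higher and the chaperone gene Hyou1 lower (−3.05, SE 1.05), so endoplasmic reticulum stress genes went both ways (9 higher, 10 lower). Of the hypoxia list, the oxygen sensor gene Egln3 lay at 3.13 (SE 1.00) and the hexokinase gene Hk1 at −2.14 (SE 0.94). Of the Notch, Wnt and hedgehog targets, Lef1 lay at 2.25 (SE 1.03) and Hey1 at 2.21 (SE 1.01). None passed over all probes or adjusted over the list alone, by limma.

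With time in controls, values were −1.71 (SE 0.48) for the neuronal gene Gap43, 2.21 (SE 0.92) for the neuronal gene Mapt and −1.92 (SE 0.65) for the oligodendrocyte factor gene Olig1. In prominin cultures they were 2.83 (SE 0.92) for Mapt, 3.54 (SE 1.19) for the myelin gene Mbp, −2.10 (SE 0.72) for Ptprz1 and −3.66 (SE 1.12) for Creld2. In the interaction they were −3.34 (SE 1.00) for Id3, −3.48 (SE 1.12) for Cldn11 and 3.75 (SE 1.20) for Ddit3. None of these passed by limma, over all probes or adjusted over the list alone.

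Apoe and Clu had higher values at 108 h in both kinds of culture: 2.87 and 2.82 in controls, 2.26 and 2.21 in prominin cultures. With the codes kept, the gene average of Clu in prominin cultures turned to −4.52, through further Clu probes that hold codes. The Clu probe behind the values given here held none. Arrays correlated at a median of 0.685 within a group, 0.695 between prominin and control arrays of the same time, and 0.658 across the times. All arrays share 1 reference, which adds to every correlation, so these values say little about how far the groups stood apart.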
